A study of Mus musculus with 6 samples.

How the data were processed

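RNA of single muscle fibers from the mouse FDB muscle was hybridised to a small spotted 2-colour array at 2 times of culture, with 3 arrays labelled day 0 and 3 arrays labelled day 3. Per the labels, more than 100 fibers were pooled for each RNA extraction with Trizol, the mRNA was amplified with an amino allyl kit, and the fiber RNA carried Cy3 while a common reference sample carried Cy5 on every array. Dyes were not swapped, so a dye effect of a feature does not cancel in its ratio to the reference, although it is shared by both days. The molecule label of the fiber RNA reads cytoplasmic RNA in experiment 2 and polyA RNA in experiments 1 and 3, with the same extraction protocol.

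Per the file headers, the authors measured each scanned image with ImaGene 5.5, and the deposited scanner files hold raw pixel intensity per spot and of its local background for each dye, not corrected for background. The deposited value table holds 1 linear ratio per spot, with cells left empty; per the labels, the ImaGene output was converted with ExpressConverter and the integrated spot signals were used. Any normalization of that table is not given in the sources used here. Set against the scanner files, its ratios followed Cy3 over Cy5 after 1 offset per array, with a median absolute log2 difference of 0.048. Spots were matched to the table on that direction, and the opposite direction was not compared. Its scale is linear and its direction was taken as fiber over reference. The origin of the offsets per array, which ran from -0.45 to 0.16 on the log2 scale, stays unknown. The column medians of the table were 0.775, 1.07 and 0.740 for day 0 replicates 1 to 3 and 1.16, 0.973 and 1.15 for day 3 replicates 1 to 3.

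The scanner files carry no gene identifier for any of the 144 spots of an array, and the value table numbers its 132 lines without names. The 22 sets of 6 consecutive lines of the table were therefore matched to spots by their pattern of ratios over the 6 arrays, by an assignment of triplets of spots with the lowest total difference. In this way 17 features were matched to 102 spots, and all 34 triplets went to the same place with integrated, mean and median signals. The mean absolute log2 difference of a matched triplet, with a cell empty on one side alone counted as 1, had a median of 0.0639. Feature 6 was matched poorly, at 0.722 and 0.404 for its triplets, where the nearest other position gave 0.720 and 0.482, so its place in the value table is uncertain. The other 5 sets of the table, nearly all empty, and 42 further spots entered no test. Since the files do not pair features with genes, no gene is named, and the gene lists, the score of fast minus slow contractile isoforms and the cell type markers fixed before the data were examined could not be computed.

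Mean pixel signals were corrected with normexp in limma 3.58.1 under R 4.3.3 with an offset of 50, and each array was normalized by loess on the matched spots, with a span of 0.75 and 4 iterations. That span was set after the layout was seen and before any test, because 17 features leave few points for a narrower one; limma's default is 0.3. No spot carried a quality mark from the image software. The log2 ratios of the 6 spots of a feature were averaged, and day 3 was compared with day 0 by limma's moderated test with Benjamini-Hochberg adjustment over the 17 features and a threshold of 0.05. A feature counted as above background on an array where its mean signal exceeded the mean local background by 2 background SDs. The rule for named features took those past the threshold with the largest change, limited to at most 2 in each direction because they have no gene names.

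Arrays were compared spot by spot before averaging. Day 0 replicates 1 and 3 differed by no more than the noise between spots and were counted as 1 sample, their mean. The comparison therefore rests on 2 day 0 and 3 day 3 samples, where the labels list 3 and 3. The numbers of the experiments were checked as possible pairs: deviations from the group mean of same-numbered arrays correlated across features with r = -0.0916, 0.235 and 0.242 in experiments 1, 2 and 3. That check used the 6 arrays as deposited. Experiments 1 and 3 thus enter with the same day 0 array, so these values cannot decide the pairing. The labels call the experiments independent replicates, without saying which animals they used, so p-values measure the spread between these arrays. The moderation pooled this spread fully: every feature had the same standard error of 0.31 on 51 degrees of freedom. By their own spread the standard errors were 0.22 for feature 5, 0.56 for feature 6, 0.40 for feature 8 and 0.42 for feature 20, and features of 1 array are not independent.

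The procedure was tested on simulated data with the real features and backgrounds, in 100 simulations with 4 changed features each and no intensity-dependent dye effect. The simulated spread between arrays was 1 value common to all features, taken over the real ones. The changed features were drawn from bright ones alone. With a span of 0.75, 48.5% of features changed by 1 log2 unit and 89.0% of those changed by 2 were called in the right direction, with mean estimates of 0.72 and 1.52, and 6.69% of unchanged features were called. The simulations held 1300 unchanged features, against 200 changed by 1 log2 unit and 200 changed by 2. False calls were therefore a larger share of all calls than 6.69%. That share lay above the adjusted p threshold of 0.05, which is meant to limit it. A span of 0.3 recovered 13.5% and 25.5% and called 3.69% of unchanged features. Median centring recovered 68.0% and 99.5% and called 2.31%, so that without a dye effect it had more right and fewer false calls than the loess used here. Loess on 17 features thus takes up part of a feature's own change. No simulated feature had a spread of its own, so the full pooling of the spread was not put to a test. Features 6 and 20 were never among the changed ones. The shares of features called therefore cannot be read for dim features or for those of unusual spread. The number of arrays limits the precision.

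Alternatives covered the background correction, the normalization, the pixel summary, the value table, dim features, the spots used in loess, a replicate block, array weights, the test, the threshold and leaving out single arrays or experiments. A further 6 were chosen after seeing the data. Spot comparisons and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.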

Results

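The question of the study, as its title and labels put it, is how muscle fibers taken out of the animal change in culture without electrical stimulation, a state that the sample titles equate with loss of the nerve. Fibers of the FDB muscle of CD-1 mice aged 4 to 5 weeks were dissociated to single fibers and kept in medium with 10% fetal bovine serum in 35 mm dishes. They were taken either after 2 h (day 0) or after 3 days (day 3), in 3 numbered experiments with 1 array per day. Each array compared the fibers with a common reference, and each gene was spotted 6 times. On the 102 spots matched to the 17 features tested, the median signal per array lay between 5554 and 11930 in the fiber channel, over a median local background of 586 to 878. Of these spots, 78 to 97 per array were above background in the fiber channel.

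Before any averaging, the arrays were compared spot by spot. Day 0 replicates 1 and 3 differed by no more than the noise between spots and were counted as 1 sample. The centres of all 144 spots had the same coordinates in both, which held for 0 spots in the other 14 pairs of arrays. For log2 ratios, the deviations of single spots from the mean of their triplet correlated across 72 spots with r = 0.874, against -0.310 to 0.238 in the other pairs. The permutation p was 1e-05, the smallest that 100000 resamples can give. In the single channels r was 0.965 for Cy3 and 0.935 for Cy5, where the other pairs reached at most 0.568 and 0.495. Spots are not independent replicates of an array. Differences between their features had a chi-square per degree of freedom of 0.886, where the lowest of the other pairs was 23.8. Day 0 is therefore represented by 2 samples and day 3 by 3.

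Between day 0 and day 3, 1 feature fell and kept its call in most of the settings tried, and 3 more passed the threshold with limits given beside them. Feature 5 (IDs 25 to 30 of the value table) fell 3.31-fold. Its log2 ratio to the reference was 0.94 ± 0.38 (SD, n = 2) at day 0 and -0.79 ± 0.12 (SD, n = 3) at day 3. The log2 change was -1.73 (SE 0.31, 95% interval -2.34 to -1.11) with an adjusted p of 1.37e-05 from limma. It did not pass with the ordinary two-sample test (adjusted p = 0.0733). Nor did it pass with a loess span of 0.3, where the change was -0.97 with an adjusted p of 0.144 from limma. On a linear scale the fibers held 1.59 and 2.32 times the reference level in the 2 day 0 samples and 0.544, 0.635 and 0.563 times in the 3 day 3 samples. The feature was above background in both channels on all 5 samples. The change lay in the fiber channel: relative to the median feature of each array, Cy3 was lower at day 3 by a log2 difference of -2.13 and Cy5 by -0.03. Within experiments 1, 2 and 3 the change was -2.09, -1.32 and -2.04, where experiments 1 and 3 share the day 0 array.

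Feature 8 (IDs 43 to 48) rose 1.97-fold, by 0.98 on the log2 scale (SE 0.31, 95% interval 0.36 to 1.60, adjusted p = 0.0103 from limma). Its log2 ratio was -0.53 ± 0.73 (SD, n = 2) at day 0 and 0.46 ± 0.15 (SD, n = 3) at day 3. The day 0 samples stood apart, at -1.04 and -0.01, and the day 3 samples lay between 0.30 and 0.59. Within experiments 1, 2 and 3 its change was 1.51, 0.60 and 1.35. The feature was above background in both channels on all 5 samples. Relative to the median feature of each array, its Cy3 signal was higher at day 3 by a log2 difference of 0.56 and its Cy5 signal was lower, with a difference of -0.12. Its reference signal varied between the day 0 arrays, with a net Cy5 signal of 14975 on replicate 1 and 3126 on replicate 2. With the fiber channel alone after quantile normalization its change was 0.99 and the adjusted p 0.154. Without normalization it was 0.73 and the adjusted p of limma 0.200; with median centring it was 0.82 with an adjusted p of 0.0703. Over its 15 alternatives that count the shared array once, other than leaving out arrays or experiments in turn, the adjusted p of limma or the ordinary two-sample test ran from 0.00267 to 0.448. The adjusted p was also above the threshold without day 3 replicate 1 (0.0528), day 3 replicate 2 (0.127) or experiment 2 (0.0944).

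A pair of dim features also passed the threshold. Feature 6, whose place in the value table is uncertain, was lower at day 3 with an adjusted p of 0.00205 from limma. Its reference signal was above background on all 5 samples. In the fiber channel it was not above background on any of the 3 day 3 samples, nor on 1 of the 2 day 0 samples. The net Cy3 signals there were below the local background, at -261, -303 and -144 on day 3 replicates 1 to 3 and -2.07 on day 0 replicate 2. The lowest fiber signal that such arrays measure exceeds its day 0 mean, so no fold is given. It did not pass without day 0 replicate 2 (adjusted p = 0.204), day 3 replicate 1 (0.0822), day 3 replicate 2 (0.112) or experiment 2 (0.298), all from limma. Feature 20 (IDs 115 to 120) was higher at day 3 with an adjusted p of 7.83e-04 from limma. Its fiber channel was above background on 1 of the 2 day 0 and 1 of the 3 day 3 samples, and its reference channel on 1 of the 2 and 0 of the 3. On day 3 replicate 3, which gave its highest ratio, the net signal was below 0 in both channels, at -422 in Cy3 and -553 in Cy5, so no fold is given for it either. Without day 0 replicate 2 its adjusted p from limma was 0.250, and without experiment 2 it was 0.298.

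**Figure D1:**
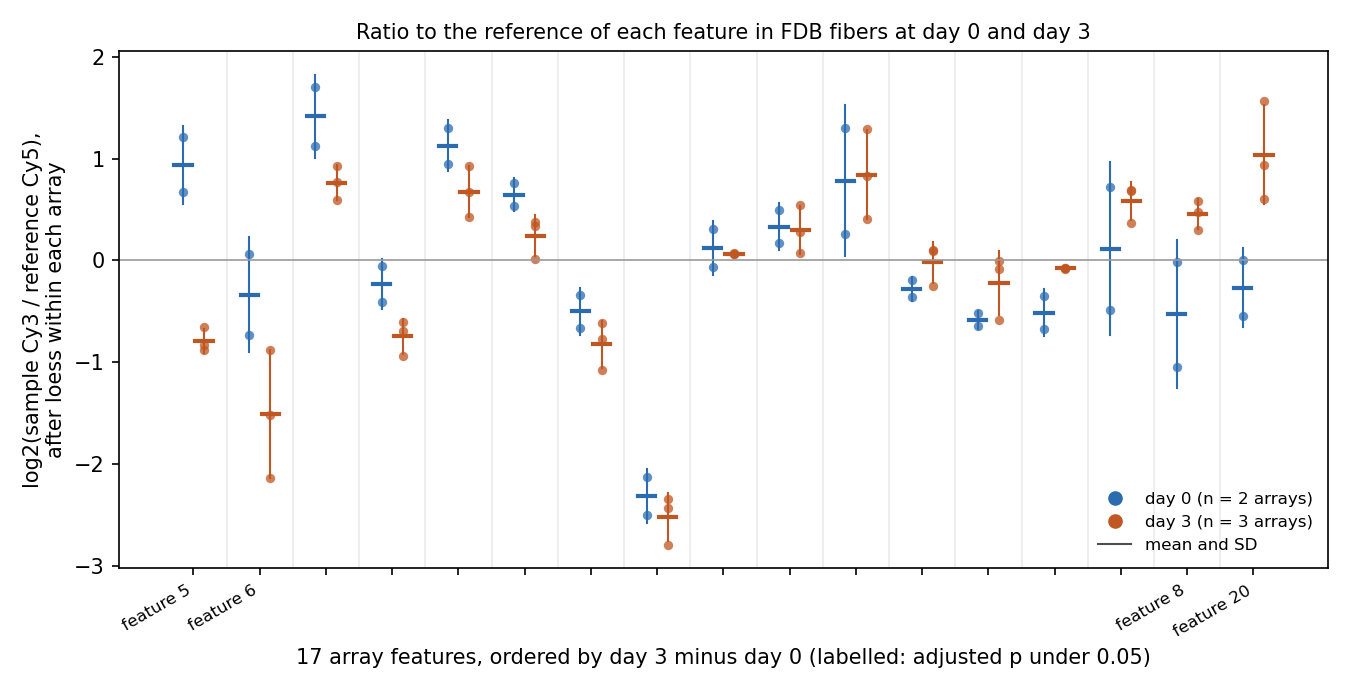
Log2 ratio of fiber (Cy3) to reference (Cy5) signal for each of the 17 features, ordered by day 3 minus day 0; each point is a sample (day 0 in blue, n = 2; day 3 in orange, n = 3), with the mean as a bar and the SD as a line. Feature 5 lies between 0.67 and 1.21 at day 0 and between -0.88 and -0.65 at day 3, while features 6 and 20 were above background in both channels on 1 of the 5 samples each, and the 13 features without a label did not pass the threshold.

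The other 13 features did not pass, with a lowest adjusted p of 0.131 from limma. Of these, 9 were above background in both channels on all 5 samples and free of saturated spots, and their log2 changes lay between -0.65 and 0.36, 3 of them positive and 6 negative. The feature at -0.65 passed as lower where the 6 arrays were used as deposited, with or without the replicate block. Another had saturated spots in Cy3 on 2 of the 6 arrays and in Cy5 on 4, and the rest were not above background throughout, so no change is given for them. One of the latter, above background in both channels on 0 of the 5 samples, passed as higher in place of feature 20 without background correction, so that the counts remained 2 and 2 with a different feature. For 6 of the 9 the 95% interval of the estimate after loess lay within 1 log2 unit of 0. All these intervals use the standard error of 0.31 pooled over features. Feature 7, one of the 6, had the widest spread of them, with SDs of 0.74 at day 0 and 0.44 at day 3. The intervals do not exclude a true change of that size, since loess brought simulated changes of 1 log2 unit to a mean of 0.72. Among the 11 features above background throughout and without saturated spots, feature 5 and feature 8 included, the day 0 and day 3 samples did not overlap for 5, 1 higher and 4 lower at day 3. Chance gives no overlap for 20% of features with 2 samples against 3, or 2.2 features here.

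The counts moved with the scaling of the arrays. After loess, 2 features passed as higher and 2 as lower; with median centring it was 0 and 1, without normalization 0 and 2, and with the fiber channel alone after quantile normalization 0 and 1. The median log2 change over the 17 features was -0.06 after loess, -0.32 with median centring and -0.41 without normalization, so that the sign of a small change depends on the scaling. Feature 5 lay beyond these shifts, with a change of -1.96 with median centring and -2.05 without normalization. The span of 0.75 used here is wider than limma's default of 0.3. With that default, added as an alternative after seeing the data, loess left 0 features past the threshold, with 1 at an unadjusted p under 0.05, and feature 5 then changed by -0.97 with an adjusted p of 0.144 from limma. The ordinary two-sample test, without moderation, also left 0, with 2 at an unadjusted p under 0.05.

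The common reference had similar profiles across features on the different samples, while the level of single features varied. Relative to the median feature of its array, the Cy5 signal of a feature had an SD over the 5 samples of 0.25 to 0.55 on the log2 scale, with a median of 0.42, over the 14 features above background in Cy5 on all of them. Feature 5 had the lowest of these SDs. Across features, the reference profiles of different samples correlated with r between 0.921 and 0.982; features are not independent replicates.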

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

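The tests in this part were chosen after the results were seen. Signal was found in 2 groups of spots that are not among the features tested. The 3 spots at grid rows 1 to 3 of column 16 had a mean net Cy3 signal of 1150 over the 5 samples (498 to 2029) and were above background on 4 of them. The 3 spots at grid rows 4 to 6 of column 1 had a mean of 1156 (791 to 1650) and were above background on 2. The other 12 such groups of 3 spots were above background on 0 samples in either channel, with net Cy3 signals between -650 and 275.

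Day 0 replicates 1 and 3 were nearly alike. One array measured 2 times is a likely explanation: the deviations of single spots correlated with r = 0.874, and all 144 spot coordinates were shared. Separate arrays of one group are argued against by a chi-square per degree of freedom of 0.886, where the other pairs gave at least 23.8. The headers of replicates 1 and 3 give the same clock time of quantification, where the other pairs of arrays lay at least 118 s apart. The headers name different images for them, and replicate 1 was dimmer in Cy3 by a log2 difference of -0.27, so the image itself was not the same. Which experiment the shared array belongs to stays open, and no biological explanation was tested.

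Feature 6 was above background in the fiber channel at day 0 on the shared array alone, with a net Cy3 signal of 1911 on replicate 1 and -2.07 on replicate 2. A weaker Cy3 gain of replicate 2 like that of 12 features with net signals above 300 on all arrays is argued against. From that gain a net signal of 1307 was predicted there, or 932 after lowering it by 1 SD of the feature differences, against a background limit of 499. That SD is of log2 ratios of Cy3 to Cy5, so the lowered value is a rough margin for Cy3. Dim features varied from replicate 1 to 2: feature 16 went from 1814 to 596, feature 17 from 1429 to 570 and feature 12 from 1296 to 1172. Feature 20 also lost its signal, from 687, which was above background, to -359. A stronger loss at low signal therefore stays open. Fewer probe molecules on those spots stay open, since the feature's Cy5 signal was low there too and predicts 533, or 380 after the same lowering. The RNA preparation of experiment 2, which has another molecule label, could also account for the missing signal of -2.07; it cannot be told apart from the array, since experiment 2 has 1 day 0 array. A fall in culture stays open as well, and was measured against a single day 0 array with signal.

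Feature 20 was higher at day 3, from signals that passed the limit of 2 background SDs in both channels on 1 sample alone. Its net signals were negative in both channels on day 0 replicate 2 and day 3 replicate 3, and positive on the other samples. Without background correction its log2 change was 0.57, with an adjusted p of 0.146, against 1.31 with it; over its 13 alternatives that count the shared array once, other than leaving out arrays or experiments in turn, the adjusted p ran from 0.00137 to 0.797. A ratio set by the background may account for the call. A true rise cannot be told apart from it here, since both channels were above background on 1 sample alone; without the correction another dim feature passed as higher in place of feature 20.

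The 5 samples can be split in 10 ways into groups of 2 and 3, too few for a share under 0.05. The real split gave 4 features past the threshold and the highest of the others gave 1; 1 of the 10 splits, the real one, gave as many.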

How the results depend on the processing

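As reported, 2 features were higher and 2 lower at day 3. The counts moved by over 1.5 times under these settings, and the cause was not tested except where stated. They were 0 higher and 1 lower with plain background subtraction, median centring, the fiber channel alone or the authors' value table, and 0 and 2 without normalization. They were 2 and 1 for features above background in at least 3 fiber channels, which leaves out feature 6 by construction and keeps feature 20 by counting the shared array 2 times. The ordinary two-sample test, with 3 degrees of freedom per feature, gave 0 and 0. Chosen after seeing the data, limma's default loess span of 0.3 gave 0 and 0, features above background in both channels on all arrays, or in the fiber channel on at least 3 of the 5 distinct samples, gave 1 and 1, and median centring of the 6 arrays as deposited gave 1 and 7. Leaving out arrays or experiments gave 0 to 2 higher and 1 to 2 lower; a lone day 0 sample was assumed to vary like the others. The lowest, 0 and 1, came without experiment 2, and it was 1 and 1 without day 0 replicate 2, experiment 1, day 3 replicate 1 or day 3 replicate 2. Of these 9 settings 5 are distinct: 2 drop 1 of the 2 scans of the shared array, which removes no sample, and leaving out experiment 1 or 3 nearly repeats leaving out its day 3 array. Feature 5 kept its call in all 5 (-2.06 to -1.68) and in 13 of the 15 other settings that count the shared array once (-2.05 to -0.97, adjusted p 3.93e-07 to 0.144). The exceptions were the span of 0.3 and the ordinary two-sample test (adjusted p = 0.0733). By the same count feature 8 kept its call in 2 of 5 and 8 of 15, feature 6 in 1 of 5 and 7 of 12, and feature 20 in 3 of 5 and 5 of 13; none changed direction. With the replicate block on 6 arrays, 2 were higher and 3 lower, as on 6 arrays without it. Same-numbered arrays did not all correlate best, which cannot decide the pairing because experiments 1 and 3 share a day 0 array. Experiments 1 and 2 with the block gave 2 and 2, as without experiment 3. Not run for lack of gene names: housekeeping centring, camera, fry and the isoform scores. No spot is marked, so keeping marked spots changes nothing. Signal over background limits features 6 and 20.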

Other observations

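The samples differed from one another in ways that belong to no comparison. Across the 17 features, which are not independent replicates, the log2 ratios of any pair of the 5 samples correlated with r between 0.490 and 0.938. The median SD of a feature was 0.26 between the 2 day 0 samples and 0.20 between the 3 day 3 samples on the log2 scale, and it was larger at day 0 for 9 of the 17 features. For feature 8 the net Cy3 signals were 8606 and 4636 on day 0 replicates 1 and 2 and 15970, 19661 and 6546 on day 3 replicates 1 to 3, where the net Cy5 signals were 11139, 10657 and 4531. For feature 5 the net Cy3 signals were 25538 and 14698 on day 0 replicates 1 and 2 and 4462, 8850 and 3912 on day 3 replicates 1 to 3, over net Cy5 signals of 8807 and 5402, and of 8452, 11090 and 6765.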
